A study of Mus musculus with 10 samples.

How the data were processed

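RNA-seq was run on marginal zone B cells, a splenic B cell population at the border of the follicle, sorted from C57BL/6 mice lacking the LDL receptor. Of the 10 libraries, 5 came from animals on standard chow and 5 from animals on a high-cholesterol diet for 8 weeks, per the labels. The series' own design text speaks of a high-fat diet instead, and the name in the sample labels is used here. Per the labels' protocols, RNA from the sorted cells was amplified over the whole transcriptome with a NuGEN kit, sheared by sonication and made into bar-coded libraries. A kit of this kind amplifies small amounts of RNA, and neither strand nor molecular identifiers are recorded in the labels. Reads from overlapping or antisense genes therefore cannot be told apart.

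The authors deposited 1 table of FPKM values, a measure of fragments scaled to transcript length and library size, with 38283 rows and 1 column per library. The submitters' processing notes name TopHat2 2.0.8, Cufflinks 2.2.1 and the mouse build GRCm38, without saying which options were used. The deposited FPKM values are estimates rather than whole reads, so read depth is unknown and no counting interval can be given. The predicted gene Gm12563 alone held 36.9% and the microRNA gene Mir5105 21.2% of the mean FPKM over all rows. Between 13238 and 14565 rows per library reached 1 FPKM.

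Columns were assigned to samples by the sample names in the labels. The values were used as deposited, with no further scaling. Rows with a mean of at least 1 FPKM over all 10 libraries were tested, which left 15071 genes, of which 10801 are annotated as protein-coding. Of these 15071 genes, 2890 were listed at 0 in some library. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with moderated variances (trend and robust), 2 groups and no covariate. P-values were 2-sided, were adjusted by Benjamini-Hochberg over all genes tested, and were held against 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Nothing in the labels says that the 5 libraries of a diet came from separate animals, so p-values measure only the spread between these samples, which may be technical.

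Gene positions are 1-based and come from the GENCODE vM21 annotation of GRCm38, joined by Ensembl gene identifier, which matched 36425 rows. The positions in the deposited table span bundles of neighbouring genes and were not used.

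Gene lists were fixed before the data were examined: 29 lists with 599 entries for pathways, B cell states and markers of other cell types that a sorting gate could hold. The lists were immediate early genes, cholesterol synthesis and uptake, LXR targets and cholesterol efflux, fatty acid oxidation, unfolded protein response, heat shock, costimulation and co-inhibition, MHC class II and antigen presentation, marginal zone identity, follicular identity, plasma cell, B cell receptor signalling, NF-kB and Toll-like receptor signalling, interferon response, cytokines, cell cycle, oxidative phosphorylation, glycolysis, ribosomal proteins, NRF2 targets, apoptosis, and markers of T cells, NK cells, macrophages, neutrophils, dendritic cells, erythroid cells, platelets and stroma. The 24 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24. Camera compares the members of a list with all other genes. Beside it stand camera with the correlation estimated for each list, limma's fry, and an exact permutation test of the list's mean per library over all 252 arrangements, whose smallest possible p is 0.00793651.

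Genes named in the text follow a rule fixed at the same time. It takes a panel of 16 genes reported whatever their result. It adds the 10 genes higher and the 10 lower with the largest fold among those that passed with non-overlapping groups, filled up by smallest unadjusted p where fewer passed. Up to 4 members with the smallest p come from each list called by camera. Predicted genes, immunoglobulin and T cell receptor segments and small RNAs were passed over. Other genes named below were chosen after their values were seen, which is said where they appear.

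The alternatives fixed beforehand were 2 other pseudocounts, 2 other filters on low values, 3 other scalings, the replicate number as a block, library weights, variance moderation without its trend and robust options, leaving out each library in turn, an estimated correlation and fry. Added after seeing the data were protein-coding genes only, removal of mt-Rnr1, the immediate early score of each library as a covariate, odd or even column number as a covariate, FPKM rescaled to the mean of the libraries' sums, and the permutation test of list means. The fit was tested on simulated data for this comparison, with 200 of 15071 genes changed in each of 20 simulations at the spread of the real libraries. It called 89.8% of the 4-fold changes and 39.7% of the 2-fold changes among genes of lower spread, and 24.8% and 2.2% among genes of higher spread. In the same simulations 4.55 unchanged genes were called per simulation. The noise was drawn independently for each gene, whereas real genes vary together (estimated correlation 0.76 in the immediate early list). The rates also depend on 200 genes being changed, so they need not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.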

Results

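The transcriptome of sorted splenic marginal zone B cells was measured in 10 libraries from mice lacking the LDL receptor, a strain in which dietary cholesterol raises plasma lipoproteins. The libraries formed 2 groups of 5, standard chow and high-cholesterol diet. The comparison asks how marginal zone B cells respond to the diet, in a study concerned with their control of follicular helper T cells. Libraries correlated with each other at a Pearson r of 0.70 to 0.82 across the 15071 genes tested, with a mean of 0.757 within a diet and 0.756 between diets. Depth is unknown because only FPKM values were deposited.

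Ldlr (ENSMUSG00000032193; GRCm38 chromosome 9, 21723483 to 21749919), the gene disrupted in this strain, was close to the floor in every library. Its level was 0.303 ± 0.293 FPKM (SD, n = 5) on chow and 0.0925 ± 0.0571 FPKM (SD, n = 5) on the high-cholesterol diet. It lay under the filter and was not tested between the diets. The highest library, chow replicate 3, held 0.797 FPKM. A gene-level value checks the genotype only in part, since some transcript can remain from a disrupted gene.

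Between the diets, 0 genes were higher and 1 gene was lower at an adjusted limma p under 0.05. At an unadjusted p under 0.05, 275 genes were higher and 447 lower. Together they made 4.79% of those tested, no more than the share of 0.05 that chance alone gives. The balance of directions depended on the scaling, with 333 higher and 313 lower after median centring and 140 and 645 when FPKM was rescaled to a fixed sum. The sum used for that rescaling rests largely on Gm12563 and Mir5105, at 36.9% and 21.2% of the mean FPKM. Leaving out 1 library gave 525 higher and 675 lower without chow replicate 4, and 573 and 589 without diet replicate 2. Without diet replicate 1 the numbers fell to 180 and 318, and with library weights they were 624 and 850. The gene that passed was mt-Rnr1 (ENSMUSG00000064337; mitochondrial genome, 70 to 1024), which encodes the small ribosomal RNA of mitochondria. It was listed at 22049, 15496, 29380, 24532 and 16512 FPKM in chow replicates 1 to 5 and at 0 in all 5 libraries of the high-cholesterol diet (limma adjusted p = 1.0e-11). The large ribosomal RNA gene beside it, mt-Rnr2 (1094 to 2675), was chosen for mention after its values were seen and was listed at 0 in all 10 libraries. The 12 mitochondrial protein-coding genes tested differed by -0.30 to 0.10 on the log2 scale, and mt-Co1, also chosen afterwards, held 4263 ± 754 FPKM on chow and 4165 ± 797 on the diet (SD, n = 5).

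Among genes that did not pass, predicted genes and small RNAs aside, the one with the smallest unadjusted p in the higher direction was Irf7 (ENSMUSG00000025498; chromosome 7, 141262706 to 141266481), a transcription factor that amplifies type I interferon. Irf7 was at 8.09 ± 2.84 FPKM on chow and 22.3 ± 5.75 on the diet (SD, n = 5). Its log2 difference was 1.38 (SE 0.25, limma adjusted p = 0.64), and all 5 diet libraries lay above all 5 chow libraries. The interferon-inducible genes Ifi27l2a (119 against 204 FPKM), Ifi27l1 (145 against 208) and Mx2 (2.87 against 6.34) were also among the 10 with the smallest p, as were Stra13, Gmfg, Papd5, Il17c, Mcrs1 and Aars, with log2 differences of 0.46 to 1.21. In the lower direction, Prdm15 (ENSMUSG00000014039; chromosome 16, 97791467 to 97851850), a zinc finger gene, had the smallest p after mt-Rnr1. It was at 20.4 ± 4.78 FPKM on chow and 7.94 ± 2.47 on the diet (SD, n = 5), a log2 difference of -1.27 (SE 0.23, limma adjusted p = 0.64). The others were Shkbp1, Atg16l1, an autophagy gene, Dctn1, Sike1, Golga1, Slc46a3, Ap2m1 and Brd7, with log2 differences of -0.96 to -0.57. The groups did not overlap for 105 genes, or 0.697% of those tested, where chance gives 0.794%.

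**Figure D1:**
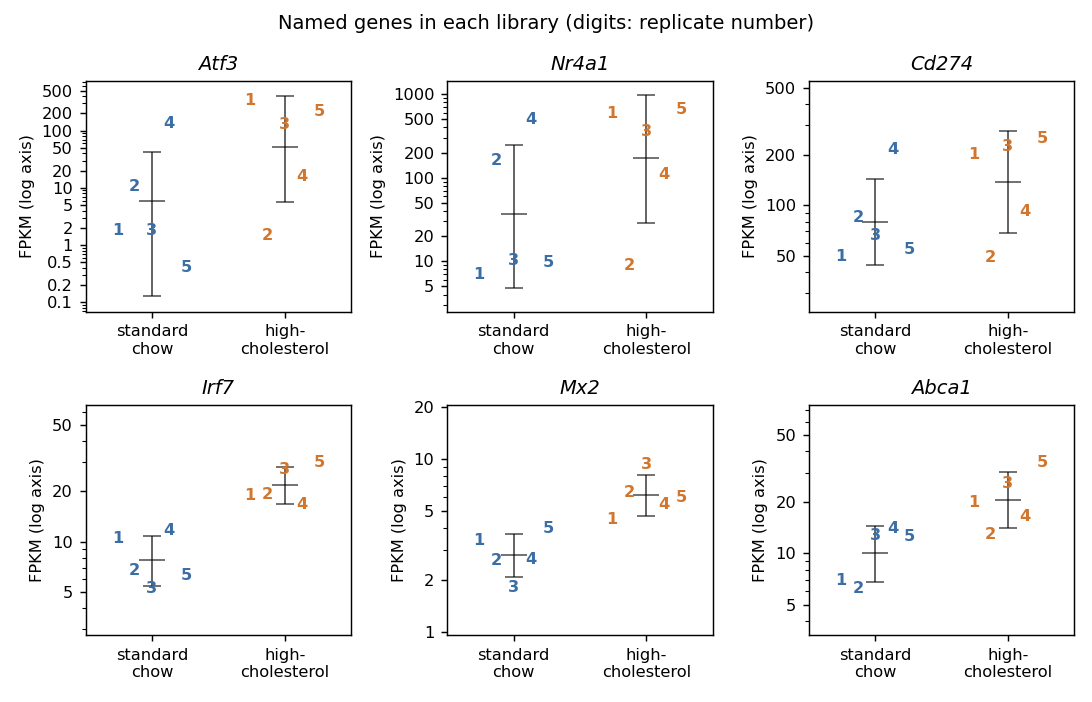
FPKM of 6 named genes in each library on log axes, by diet, with each digit marking a replicate number and the bar showing the mean ± SD of log2(FPKM + 1) turned back to FPKM (n = 5). The diets do not overlap for Irf7 and Mx2, whereas for Atf3, Nr4a1 and Cd274 both diets hold low libraries and high ones.

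Genes of the interferon response were higher than the other genes on the high-cholesterol diet by camera at its preset correlation. Of 28 members tested, 24 had higher estimates and 4 lower, with a median log2 difference of 0.22, and camera called the list (adjusted p = 3.8e-07). With an estimated correlation the call was lost (p = 0.037, adjusted p = 0.698). Over all genes tested 0 members passed, and 5 passed when adjusted over the list alone, namely Irf7, Mx2, Oasl2, Zbp1 and Oas2, the last of which is named after its value was seen. Oasl2, of the oligoadenylate synthetase family of antiviral genes, was at 3.76 ± 1.60 FPKM on chow and 8.56 ± 2.42 on the diet (SD, n = 5). Zbp1, a sensor of nucleic acids in Z conformation, was at 22.5 ± 4.62 and 32.9 ± 3.90 FPKM (SD, n = 5), and Mx2, an interferon-inducible gene that the annotation lists as a polymorphic pseudogene, at 2.87 ± 0.815 and 6.34 ± 1.82 (SD, n = 5). Fry, which does not compare a list with other genes, gave an adjusted p of 0.635 for a shift in 1 direction and 0.0106 for changes in either direction. An exact 2-sided permutation test of the list mean gave p = 0.0476 before and 0.571 after adjustment over the 24 lists. The mean of the T cell markers lay higher on the diet as well, at 1.88 against 1.59 on the log2 scale (exact permutation p = 0.0238, 0.571 adjusted over the lists). Its lowest library, chow replicate 3, stood at 1.22, against 1.63 to 1.74 in the other chow libraries.

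**Figure D2:**
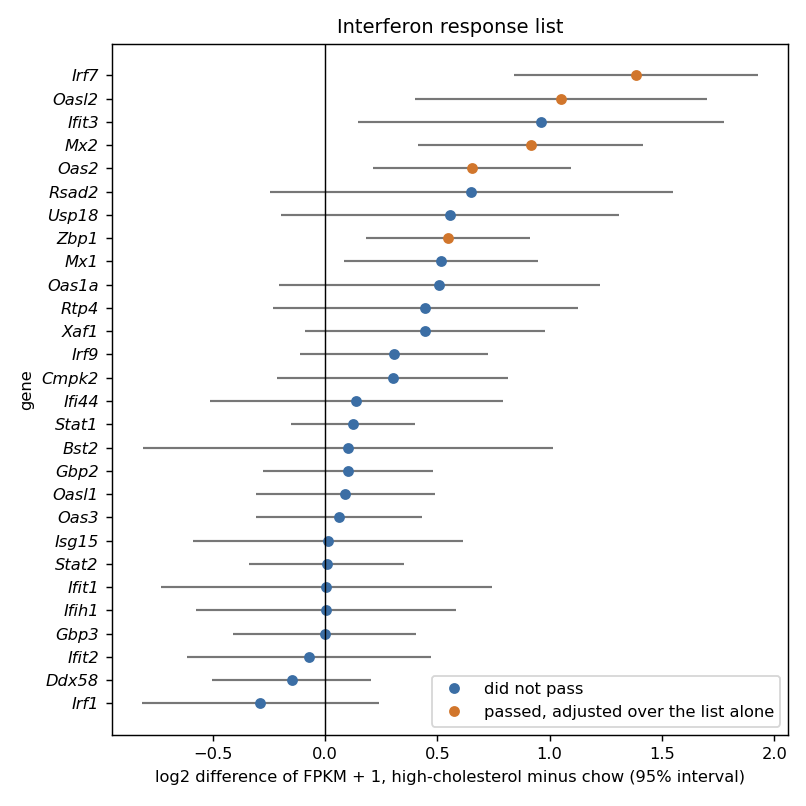
Log2 difference of each tested member of the interferon list (high-cholesterol diet minus chow, FPKM + 1) with its 95% interval from limma, 5 libraries per diet. The 5 orange genes passed when adjusted over the list alone, and 24 of 28 points lie above 0.

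Immediate early genes, which are induced within minutes of stimulation, had 27 of 29 tested members with higher estimates on the high-cholesterol diet and a median log2 difference of 1.81. Camera called the list (adjusted p = 7.0e-09), and with an estimated correlation the call was lost (adjusted p = 0.698). Of its members, 0 passed over all genes and 0 when adjusted over the list alone. Atf3 (ENSMUSG00000026628; chromosome 1, 191170296 to 191218039), a stress-induced transcription factor, was at 29.7 ± 58.4 FPKM on chow and 140 ± 141 on the diet (SD, n = 5), a log2 difference of 2.90 (SE 1.69, limma adjusted p = 0.876). Nr4a1, an orphan nuclear receptor, was at 137 ± 212 and 344 ± 285 FPKM, Myc at 296 ± 197 and 530 ± 251, Ier5 at 88.9 ± 53.1 and 136 ± 53.7, and Ier2 at 18.3 ± 18.7 and 34.8 ± 19.7 (SD, n = 5). The libraries within each diet stood far apart. The list mean was 3.22, 6.05, 3.72, 7.17 and 3.10 on the log2 scale in chow replicates 1 to 5, and 7.40, 3.40, 6.90, 5.90 and 7.53 in replicates 1 to 5 of the diet. An exact permutation test of the list mean gave p = 0.190.

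Cd274 (ENSMUSG00000016496; chromosome 19, 29367455 to 29388095) encodes PD-L1, a ligand that restrains T cells through PD-1. It was at 94.0 ± 68.8 FPKM on chow and 163 ± 87.9 on the diet (SD, n = 5), a log2 difference of 0.78 (95% interval -0.42 to 1.98, limma adjusted p = 0.876). The 4 libraries with the most Cd274, at 199.9 to 249.6 FPKM, were chow replicate 4 and diet replicates 1, 3 and 5, which also held the highest immediate early means. With the immediate early score of each library as a covariate, chosen after seeing the data, the log2 difference of Cd274 was 0.01. The list mean behind that score was 4.65 on chow and 6.23 on the diet. Here and below, such a fit can therefore also remove part of a response to the diet. Pdcd1lg2, encoding the related ligand PD-L2, differed by 0.44 (95% interval -0.11 to 0.99), and Icosl, the ligand of ICOS on T cells, by -0.03 (95% interval -0.28 to 0.22). Of 16 costimulation and co-inhibition members tested, 6 had higher and 10 lower estimates, 0 passed either adjustment, and camera did not call the list (adjusted p = 0.644). The panel, this list and the immediate early list were chosen with the study's subject in mind and are not independent of it.

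Genes of cholesterol handling did not pass, although 2 sterol exporters had higher estimates. Abca1 (ENSMUSG00000015243; chromosome 4, 53030787 to 53159895), which exports cholesterol from cells and is a target of the sterol-sensing receptor LXR, was at 10.5 ± 3.64 FPKM on chow and 22.0 ± 8.39 on the diet (SD, n = 5). Its log2 difference was 0.98 (95% interval 0.31 to 1.65), with an unadjusted limma p of 0.0083 and an adjusted p of 0.876. Abcg1, a second exporter, was at 56.0 ± 22.5 and 105 ± 50.9 FPKM (SD, n = 5), a log2 difference of 0.82 that became 0.38 with the immediate early score as a covariate. The LXR list had 12 of 20 members higher (median 0.08, camera adjusted p = 0.238). Genes of cholesterol synthesis and uptake had 9 of 23 members higher (median -0.06, camera adjusted p = 0.632), and Hmgcr, the rate-limiting enzyme of synthesis, was at 21.6 ± 3.66 and 20.5 ± 4.03 FPKM (SD, n = 5). In the list of fatty acid oxidation, 6 of 14 members were higher (median -0.09, camera adjusted p = 0.943), with the median and mean below 0 and camera's direction up.

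Camera also called cytosolic ribosomal proteins and NRF2 targets higher, and both calls were lost with an estimated correlation (adjusted p = 0.698 for each list). Of 33 ribosomal protein genes, 32 had higher estimates, with a median log2 difference of 0.13 (camera adjusted p = 1.4e-06), and 0 passed over all genes or adjusted over the list alone. Rpl3 was at 325 ± 36.7 FPKM on chow and 418 ± 51.1 on the diet, and Rpl4 at 1010.1 ± 61.2 and 1178 ± 91.6 (SD, n = 5), with Rpl10 and Rps4x at log2 differences of 0.17 and 0.23. Ribosomal protein genes have many near-identical pseudogenes, so their values are uncertain. NRF2 targets, genes of the antioxidant response, had 11 of 13 members higher (median 0.14, camera adjusted p = 0.0443), and 0 passed over all genes or adjusted over the list alone. The ferritin light chain gene Ftl1 was at 279 ± 88.7 and 375 ± 57.4 FPKM, the ferritin heavy chain gene Fth1 at 826 ± 233 and 1024 ± 177, and Sod1, a superoxide dismutase, at 363 ± 55.7 and 418 ± 14.3 (SD, n = 5), and Nfe2l2, encoding NRF2 itself, differed by 0.29. Both calls were also lost when FPKM was rescaled to a fixed sum (camera adjusted p = 0.0587 for ribosomal proteins and 0.265 for NRF2 targets), a sum that rests largely on Gm12563 and Mir5105. The NRF2 call was also lost without chow replicate 1, 2 or 5 or without diet replicate 1, 3 or 4 (camera adjusted p = 0.0606 to 0.215), and with quantile normalization (0.0740). With the immediate early score of each library as a covariate, chosen after seeing the data, the NRF2 call was lost (camera adjusted p = 0.437) and Nfe2l2 turned to -0.014.

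**Figure D3:**
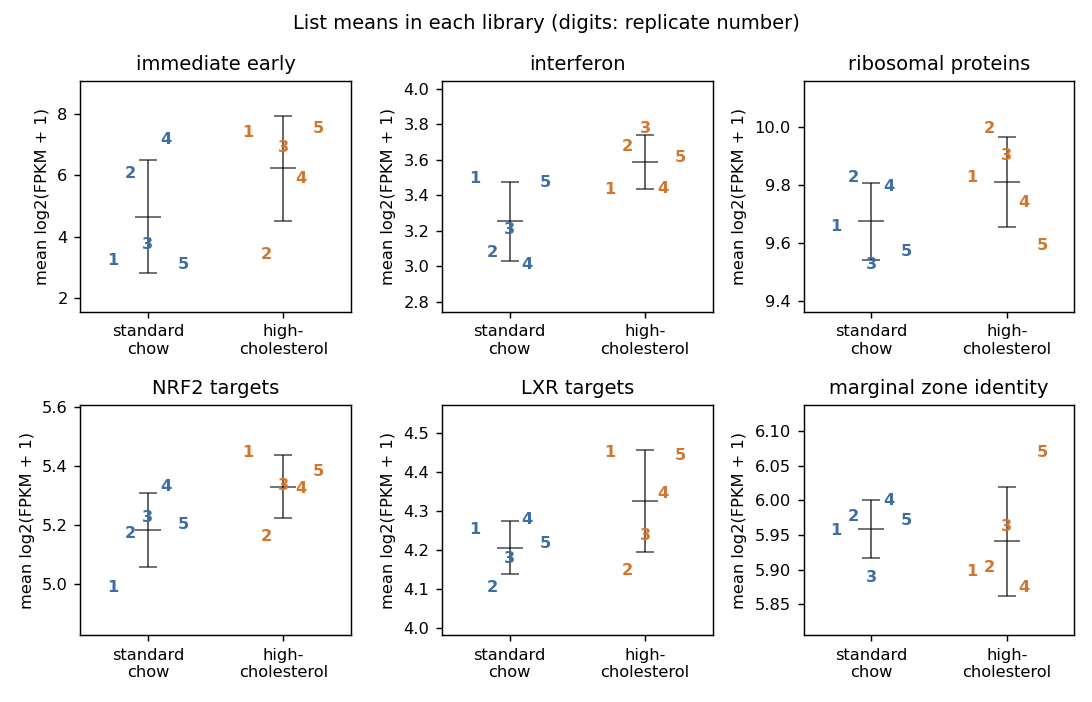
Mean log2(FPKM + 1) of the tested members of 6 gene lists in each library, by diet, with digits marking replicate numbers and bars the mean ± SD (n = 5). Immediate early means range from 3.10 to 7.17 within chow, while interferon means are 3.25 ± 0.22 on chow and 3.59 ± 0.15 on the diet.

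Markers of the marginal zone state did not pass the test between the diets. Cr2, the complement receptor CD21, was at 331 ± 71.5 FPKM on chow and 275 ± 61.1 on the diet, and Cd1d1, which presents lipids to NKT cells, at 139 ± 30.1 and 133 ± 25.5 (SD, n = 5). A second annotated row overlaps Cr2, so the split of its reads is uncertain. Fcer2a, the follicular marker CD23, was at 29.8 ± 10.7 and 32.5 ± 6.32 FPKM (SD, n = 5). The marginal zone list had 10 of 27 members higher (median -0.08, camera adjusted p = 0.632) and the follicular list 11 of 16 (median 0.08, camera adjusted p = 0.620). Plasma cell genes had 8 of 14 higher (camera adjusted p = 0.625), and B cell receptor signalling 9 of 25 (camera adjusted p = 0.979), with the median and mean below 0 and camera's direction up. In none of these 4 lists did a member pass over all genes or adjusted over the list alone.

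Receptors and cytokines of innate activation did not pass either. Tlr9, a receptor for unmethylated DNA, was at 64.1 ± 6.95 FPKM on chow and 47.9 ± 9.06 on the diet (SD, n = 5), a log2 difference of -0.42 (95% interval -0.74 to -0.10, limma adjusted p = 0.876). Tlr4, the endotoxin receptor, was at 21.5 ± 11.8 and 17.3 ± 3.39 FPKM (SD, n = 5), and its difference turned from -0.15 to 0.10 without chow replicate 1. Il10 was at 2.34 ± 2.35 and 6.89 ± 4.79 FPKM (SD, n = 5), with a log2 difference of 1.18 that became 0.20 with the immediate early score as a covariate. Il6 was listed at 0 in 9 of 10 libraries and at 0.049 FPKM in chow replicate 5. The NF-kB and Toll-like receptor list had 17 of 29 members higher (camera adjusted p = 0.620), and the cytokine list 7 of 10 (camera adjusted p = 0.328), with 0 members of either passing over all genes or adjusted over the list alone.

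Of the remaining pathway lists, camera called 0. Members higher were 16 of 21 for MHC class II and antigen presentation (adjusted p = 0.109), 9 of 12 for heat shock (0.238), 13 of 24 for cell cycle (0.254), 10 of 18 for glycolysis (0.422), 8 of 14 for apoptosis (0.377), 14 of 26 for oxidative phosphorylation (0.620) and 9 of 23 for the unfolded protein response (0.523). For oxidative phosphorylation the mean lay below 0 and the median above it, and for the unfolded protein response the reverse. Leaving out 1 library gave a camera call for antigen presentation (adjusted p = 0.0341 without chow replicate 4, 0.0093 without diet replicate 3 and 0.0272 without diet replicate 5), cell cycle (0.0232 without chow replicate 4), heat shock (0.0028 without chow replicate 2) and oxidative phosphorylation (0.0272 without diet replicate 5). Members passing over all genes or adjusted over the list alone numbered 0 in each of these lists.

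Few markers of other cell types reached the filter of 1 FPKM. The T cell list had 7 of 18 entries above the filter, of which 5 had higher estimates (camera adjusted p = 0.238), the macrophage list 5 of 22 with 3 higher (0.444), and the dendritic cell list 7 of 14 with 3 higher (0.814). NK cell, neutrophil, erythroid, platelet and stromal lists had 2, 2, 3, 2 and 3 members above the filter, too few for the test. The mean of the T cell markers was 1.59 ± 0.21 on the log2 scale on chow and 1.88 ± 0.15 on the diet, with the smallest exact permutation p of the lists tested (0.0238, and 0.571 after adjustment over the 24 lists). Chow replicate 3 was set apart at 1.22, against 1.63 to 1.74 in the other chow libraries. The mean of the 2 NK cell markers was 1.55 ± 0.22 and 1.94 ± 0.35, with an exact permutation p of 0.103. As examples chosen afterwards, Cd3e reached at most 0.149 FPKM and C1qa 0.511 FPKM in any library. Other members were higher. The highest mean FPKM over all 10 libraries was 8.67 in the T cell list (Lck), 20.6 in the macrophage list (Cd68) and 4.36 in the NK cell list (Prf1). It was 60.7 in the stromal list (Pecam1) and 624 in the dendritic cell list (Ly6d). The cells these transcripts came from were not tested. Members of these lists that passed over all genes or adjusted over the list alone numbered 0.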

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

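Of 144 checks of a single library against the other 4 of its diet, over the named genes and the list means, 8 found a library set apart, and chance gives about 1 in 20. Among the 8, the flag of Il6 was fixed in advance by its zeros. The figure given for each is the gap to the nearest library as a share of the whole range, against a critical share of 0.71. The genes and the list means were fixed by rule, and no explanation was tested for them.

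Il6 was at 0.049 FPKM in chow replicate 5 and listed at 0 in the other chow libraries, a share of 1. With all the others at 0 the share is 1 whatever the remaining value, so this flag tells nothing. Aars, a tRNA synthetase gene, was at 7.18 FPKM in chow replicate 3 against 9.94 to 10.3 in the others (share 0.908). Ier5, an immediate early gene, was at 183 FPKM in chow replicate 4 against 57.8 to 72.6 (share 0.804). Among the libraries of the high-cholesterol diet, Slc46a3 was at 25.9 FPKM in replicate 2 against 18.4 to 19.9 (share 0.772) and Atg16l1 at 22.0 FPKM in replicate 3 against 18.3 to 19.2 (share 0.738).

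On the log2 scale, the mean of the apoptosis list was 3.60 in diet replicate 2 against 4.14 to 4.33 in the other diet libraries (share 0.732). The cell cycle mean was 2.28 in the same library against 2.63 to 2.77 (share 0.719). The mean of the T cell markers was 1.22 in chow replicate 3 against 1.63 to 1.74 in the other chow libraries (share 0.791).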

How the results depend on the processing

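The fits on protein-coding genes, without mt-Rnr1, with the immediate early score or odd and even column numbers as a covariate, with FPKM rescaled to the mean of the libraries' sums, and the permutation of list means were chosen after the results were seen; the other alternatives were planned. Causes of the changes below were not tested unless stated. Depth is unknown, so no alternative speaks to it.

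Genes higher numbered 0 in every fit that kept all 10 libraries, and 0 to 2 when 1 library was left out: 1 without chow replicate 5 and without diet replicates 1 and 4, and 2 without diet replicate 5. Genes lower numbered 1 to 2 when 1 library was left out, with 2 without diet replicates 2 and 3. They numbered 0 on protein-coding genes alone and 0 without mt-Rnr1, both by construction, and 1 in the other fits except the replicate block. After each diet's mean was subtracted from every gene, same-numbered libraries correlated at -0.117 to 0.0082. By that measure 0 chow libraries correlated best with their own number, which gave no sign that the replicate numbers pair the samples. With the replicate block 2 genes were lower and 3 lists were called, the NRF2 call being lost. Genes at an unadjusted p under 0.05 numbered 275 higher and 447 lower, with a median log2 difference of all genes of -0.03. They numbered 140 and 645 (median -0.10) with FPKM rescaled to a smaller fixed sum (TPM), which also gives the pseudocount more weight, and 138 and 648 (median -0.13) with the mean of the sums, which keeps its weight. They numbered 333 and 313 after median centring and 624 and 850 with library weights. With 1 library left out they numbered 525 and 675 without chow replicate 4, 573 and 589 without diet replicate 2, and 180 and 318 without diet replicate 1.

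Camera called 4 lists as reported, 2 with either rescaling of FPKM, and 0 with an estimated correlation; fry's test of a shift in 1 direction and the permutation of list means called 0 as well. Fry's test of changes in either direction called the interferon list (0.0106). The interferon list was called under all other scalings, filters, pseudocounts and left-out libraries (adjusted p from 2.6e-09 to 4.2e-04), and so was the immediate early list (1.4e-14 to 2.8e-05). With quantile normalization the NRF2 call was lost (0.0740) and with the odd and even numbers too (0.0581), and with the immediate early score its adjusted p was 0.437. Antigen presentation was called with the immediate early score (0.0319) and with the odd and even numbers (0.0480), and heat shock and cell cycle with library weights (0.0280 each).

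The lists and genes that reversed passed neither as reported nor in the fit that reversed them. The Ldlr difference was -0.23, and -0.87 and -1.60 with pseudocounts of 0.1 and 0.01. B cell receptor signalling turned down with these pseudocounts (camera adjusted p = 0.955 and 0.933), without a filter (0.786), with quantile normalization (0.744), FPKM rescaled to a fixed sum (0.725) or the mean sum (0.630), protein-coding genes (0.988), fry (0.880) and permutation (0.952). Dendritic cell markers turned up without a filter (0.786). With library weights cholesterol synthesis turned up (0.930) and fatty acid oxidation down (1.00, also 0.899 by fry and 0.882 by permutation). By permutation of means the unfolded protein response turned up and oxidative phosphorylation down (0.952 each), the latter also with the mean sum (0.996). With the immediate early score, heat shock, plasma cell, NF-kB and cell cycle lists turned down and costimulation up (0.885 each), and the follicular list turned down (0.437). In the same fit Cd1d1 was at 0.16, Fcer2a at -0.057, Tlr4 at 0.12 and Nfe2l2 at -0.014. With the odd and even numbers Cd1d1 was at 0.049 and costimulation turned up (0.974). Icosl was at 0.010 after median centring.

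With 1 library left out, log2 differences ranged from -0.089 to 0.019 for Icosl, -0.18 to 0.027 for Hmgcr, -0.18 to 0.043 for Cd1d1 and -0.43 to 0.10 for Tlr4. Camera adjusted p ranged from 0.457 to 0.954 for cholesterol synthesis, 0.698 to 0.993 for fatty acid oxidation, 0.547 to 0.957 for costimulation, 0.640 to 0.957 for B cell receptor signalling, 0.0272 to 0.836 for oxidative phosphorylation and 0.584 to 0.992 for dendritic cell markers.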

Other observations

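The splits of the libraries, the fit with the immediate early score, the permutation tests, the mitochondrial comparisons and the gap of non-coding genes were chosen after the results were seen, while the other scalings, the left-out libraries and the estimated correlation were planned. The genes named in this paragraph were chosen after their values were seen. Immunoglobulin transcripts did not pass between the diets. Ighm, the heavy chain of IgM, was at 2852 ± 335 FPKM on chow and 2764 ± 309.8 on the diet, and Igkc, the kappa light chain, at 10215 ± 749 and 10094 ± 999 (SD, n = 5). Ighg3 was at 19.9 ± 3.77 and 30.0 ± 12.0 FPKM (SD, n = 5), a log2 difference of 0.49. Tnfrsf13c, the receptor for the survival factor BAFF, was at 267 ± 28.6 FPKM on chow and 207 ± 15.3 on the diet (SD, n = 5), with an unadjusted limma p of 0.0079 and an adjusted p of 0.876. Xbp1, a transcription factor of secretory cells, was at 35.5 ± 3.69 and 27.9 ± 4.46 FPKM, while Slamf7, an adhesion receptor, was at 37.4 ± 16.2 and 66.2 ± 24.3 (SD, n = 5), neither passing.

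The count of genes between the diets was 1, and 43 of 100 splits of the 10 libraries into 5 and 5, out of 126 different ones, gave as many, counting the diets' own. The highest other split gave 528. Chance can therefore not be excluded for that count. A split that calls this many genes points to a structure among the samples that the diets do not follow.

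The interferon list was called higher on the high-cholesterol diet by camera at its preset correlation, a call lost with an estimated one (adjusted p = 0.698). The call held under the 3 other scalings that were planned (largest camera adjusted p = 1.5e-06) and with 1 library left out (largest 4.2e-04). With the immediate early score as a covariate it held too (camera adjusted p = 2.2e-11). Splits that mix the diets also gave small camera p at this correlation. These fits alone therefore cannot decide against scaling, a single library or the immediate early state as a cause. The list means of chow replicates 2, 3 and 4 (3.08, 3.21, 3.01) lay below all 5 diet libraries (3.43 to 3.78), which argues against a single library. Within chow, replicates 2 and 4 had the highest immediate early means (6.05, 7.17) and the lowest interferon means. That argues against the immediate early state there. On the diet, replicates 2 and 3 had the highest interferon means (3.67, 3.78), at immediate early means of 3.40 and 6.90. Differences of the list mean within odd and within even column numbers averaged 0.36 on the log2 scale (exact permutation p = 0.04 over 100 arrangements). In even columns diet replicates 1, 3 and 5 (3.43, 3.78, 3.61) lay above chow replicates 2 and 4 (3.08, 3.01). In odd columns diet replicates 2 and 4 (3.67, 3.44) overlapped chow replicates 1, 3 and 5 (3.50, 3.21, 3.47). An alternation of the column numbers is constant within each of these sets, so it cannot by itself give the gap within the even columns. The gap therefore argues against an alternation as the whole cause. It rests on few libraries, and the odd columns, which overlapped, add little. Chow holds columns 1 to 5 and the diet 6 to 10, so an order by block is confounded with the diet and open. Chance was not excluded at a share of 0.05. Of 100 splits, 5 gave a camera p as small as the real 3.2e-08, counting the diets' own. The smallest other p, 2.1e-11, came from the split of chow replicate 1 with diet replicates 2 to 5. That split differs from the diets only by exchanging replicate 1 of each. Those at 7.0e-10 and 1.2e-08 only exchange chow replicate 1 with diet replicate 4 and 5, respectively. Another, at 1.6e-08, joined chow replicates 1 and 5 with diet replicates 2, 3 and 5. Splits that exchange 1 library keep most of the diet grouping, so the share of 5 in 100 is a poor guide to chance. A response to the diet may account for the pattern and remains a hypothesis. T cell markers lay higher too (1.88 against 1.59, exact permutation p = 0.0238, adjusted 0.571), with chow replicate 3 set apart at 1.22, and were not tested as its source.

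Immediate early genes were called higher on the diet by camera, a call lost with an estimated correlation (adjusted p = 0.698; exact permutation p of the list mean 0.190). Chance was not excluded, as 16 of 100 splits, the diets' own among them, gave a camera p as small as the real 2.9e-10, the smallest other being 6.3e-28. The split that called 528 genes separates the 5 libraries with the lowest list means, at most 5.90 on the log2 scale, from the 5 with the highest, at least 6.05. It also sets odd column numbers (chow replicates 1, 3 and 5, diet replicates 2 and 4) against even ones, and since it follows the list itself it gives no independent test of an order. A response to the diet stays open for this list, and the labels record no day or order of handling that would allow a test of it.

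For mt-Rnr1, a loss of mitochondrial RNA would lower the mitochondrial protein-coding genes too, but their median log2 difference was -0.14 over the 12 tested. A failed estimate in the deposited table may explain its zeros, since mt-Rnr2, which every cell uses, was listed at 0 in 10 libraries. The protein-coding gene mt-Nd4l, also chosen afterwards, lay under the filter, at 0.457 FPKM in diet replicate 3 and 0 in every other library. Its neighbour mt-Nd4 held a mean of 1519 FPKM on chow and 1253 on the diet. Why the zeros of mt-Rnr1 follow the diet was not tested, and processing of the groups in separate runs stays open.

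For the other lists called by camera, counting the diets' own split, 20 of 100 splits gave a p as small for ribosomal proteins (real 1.8e-07, smallest other 8.1e-24) and 5 of 100 for NRF2 targets (real 0.0074, smallest other 0.0021), so chance was not excluded for either at a share of 0.05. For NRF2 targets, the splits with a camera p of 0.0021, 0.0027 and 0.0065 only exchanged chow replicate 4 with 1 diet library. They keep most of the diet grouping, so that share is a poor guide to chance. Long non-coding genes lay below protein-coding genes on the diet, with a gap of medians of -0.09 on the log2 scale. A gap as large was found in 16 of 100 splits, the diets' own among them, the largest other being 0.158, so chance was not excluded there either.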
